A study of Mus musculus with 12 samples.

How the data were processed

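Per the labels, fetal dorsal telencephalon of C57BL/6J mice was taken at gestational day 14.5, without ganglionic eminences, cortical hem and meninges, from dams that had spent 50 minutes in ethanol vapour or control air on gestational day 12.5. Cells were fixed in methanol, and 10,000 were loaded per sample for 10x Genomics 3 prime libraries. The 12 samples came from alcohol dams 9, 12 and 1 and control dams 10, 2 and 8, each with 1 male and 1 female sample, so replicates of a treatment are separate dams. The number of fetuses in a sample is not given in the sources used here. The deposited matrices hold UMI counts per gene and barcode, made by the authors with Cell Ranger on the mm10 build; per the file headers the software version is 3.1.0, and the annotation release, strand setting and barcode calling are not given in the sources used here. The 31053 genes included 35 symbols shared by more than 1 gene, which were kept apart by Ensembl ID. An aggregate matrix of 12 libraries in the series was not used, since its libraries could not be matched to the samples.

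Barcodes were kept with at least 500 detected genes and at most 10% mitochondrial UMIs. Scrublet was run per sample in scanpy 1.11.5 with 2 simulated doublets per cell, and the cells with the highest scores were removed at 0.8% per 1000 barcodes, which took 5.99% to 14.9% of a sample. Of 130029 barcodes 94540 stayed, 53.1% to 82.8% of a sample, with 21680614 to 66922499 UMIs per sample and 1685 to 3176 median genes per cell; barcodes above the mitochondrial limit made up 4.38% to 40.0%. Counts were scaled to 10000 per cell and logged, 2000 variable genes were chosen without mitochondrial, ribosomal, haemoglobin, Xist, Tsix and Y genes, and 30 principal components and 15 neighbours were used for Leiden clustering at resolution 1.0 without integration of batches. Python 3.11.15, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9 and matplotlib 3.10.9 were used.

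Clusters were named from marker lists fixed before the data were examined, while the thresholds of naming were set after the clusters had been seen: a log2 fold of at least 0.5 over the other cells with 10 CPM added, at least 3 raised markers, and markers among the top 10 genes. Clusters with 90% of cells from 1 sample, or with low depth (under 1/3 of the sample median) and no marker of the class among their top genes, stayed unnamed. Classes held 26102 radial glia, 15875 intermediate progenitors, 33420 excitatory neurons, 4894 interneurons, 1135 Cajal-Retzius cells, 409 microglia and macrophages, 311 erythroid, 220 endothelial and 142 mural cells, 82508 in all. Unnamed were cluster 0, shallow and neuron-like (4.63% of kept cells in alcohol and 9.96% in control dams), the dividing cluster 3 nearest to intermediate progenitors (4.10% and 3.38%), cluster 13 with no raised markers (1.60% and 1.06%), cluster 18, with 96% of its cells from alcohol female 1 (0.0880% and 0.00209%), and cluster 9 (0.0178% and 0.00838%).

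UMI counts were summed over the cells of a class and compared with edgeR 4.0.16 (TMM, filterByExpr, quasi-likelihood F test) in R 4.3.3, with Benjamini-Hochberg adjusted p under 0.05 as threshold. The dam was the replicate: male and female samples were summed for the comparisons by dam, the comparisons in males and in females used 1 sample per dam, and the interaction used a 4-group model of 12 samples. Raw counts were summed, so the deeper sample of a dam weighs more. In all cells, intermediate progenitors and excitatory neurons the female sample held more UMIs than the male one in each alcohol dam. It held fewer in each control dam. In excitatory neurons it held 20929505 against 7787172 in dam 9, and 8429821 against 12586593 in dam 10. Values by dam thus compare different mixtures of the sexes. Male against female used 12 samples with treatment as covariate. Values per gene are log2 changes with SE from the fit and mean ± SD of TMM-scaled CPM over dams or samples. Classes with at least 20 cells in every dam were compared. Whether the male and female sample of a dam resemble each other was checked once, from the correlation of their deviations from the group means: 0.417, 0.753, 0.306, 0.232, 0.816 and 0.199 for dams 9, 10, 12, 1, 2 and 8, against a mean of −0.0891 between dams, so values blocked by dam are given beside the interaction and sex results where they differ. Of the title numbers, alcohol and control dams share 1 and 3 (correlations 0.539 and 0.00305, against −0.0786 without a shared number). Of the description numbers, whose meaning for control dams is not given, they share 260 (dams 9 and 10) and 210 (dams 1, 2 and 8). No pair of replicates was a duplicate (chi-square per degree of freedom 39.3 to 451 over 12 pairs). The first principal component of the 6 dams held 60.4% of the variance and ran from control dam 10 (−41.4) to control dam 2 (56.4), with the alcohol dams between them.

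Shares of kept cells were averaged over the male and female sample of a dam and compared by a two-sided exact permutation of 3 against 3 dams, whose smallest possible p is 0.1. The 24 gene lists were alcohol and acetaldehyde metabolism, oxidative stress response, unfolded protein and integrated stress response, p53 targets and apoptosis, heat shock proteins, immediate early genes, S phase, G2 and M phase, glycolysis and hypoxia, nuclear respiratory chain subunits, mitochondrially encoded genes, ribosomal proteins, Notch, Wnt, Hedgehog and retinoic acid signalling, cholesterol synthesis, insulin and growth factor signalling, imprinted genes, interferon response, axon guidance and adhesion, glutamate and GABA receptors, DNA methylation and chromatin, and haemoglobins. They were tested with camera in limma 3.58.1 at a preset correlation of 0.01, again with an estimated correlation, and with fry, adjusted over the lists of a comparison. Lists, tests, filters and the rule for naming genes were fixed before the data were examined. By that rule the genes named are those past the threshold with at least 10 CPM and the largest changes (12 each way by dam in the 3 large classes, 5 elsewhere); where fewer than 5 pass, those with the smallest p (5 each way, or 3); up to 4 members of each list with the smallest p; and fixed X and Y genes with the 5 autosomal genes of smallest p for sex. Genes called only by an alternative are named as examples.

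On simulated counts with the dispersions of the real libraries and 200 changed genes, the test recovered 64% of log2 changes of 1 in radial glia and 50% in excitatory neurons by dam, 53% in radial glia of males, 99% for the interaction of excitatory neurons with dam as block and 85% for sex; changes of 2 were recovered at 98% or more. Unchanged genes called numbered 6 to 11 in each. The changed genes were picked among those with a mean of at least 10 CPM, so recovery of lower genes was not simulated. Each gene was drawn on its own, without differences between samples that many genes share, so these rates do not cover such differences. Divisions of the real dams other than treatment gave up to 1032 genes, in excitatory neurons of males. Alternatives planned before the data were examined were DESeq2 1.42.0, RLE scaling, no filter on low counts, no doublet removal, stricter cells (1000 genes, 5% mitochondrial), resolution 0.5, each replicate left out, blocks by title number, description number and dam, a 12-sample model with sex as covariate, a 4-group model, another denominator of shares, and each sex alone. After the counts of 0 had been seen 7 alternatives were added: the median mitochondrial share as covariate, the same with dam as block, cells with at most 20000 UMIs, no shallow clusters, no clusters with 1/3 or more of their cells from 1 sample, cluster 3 put into intermediate progenitors, and list medians with each replicate left out. All 10 divisions of the 6 dams and 100 divisions of the 12 samples were also run. Correlations were tested by exact permutation, within groups (1296 arrangements) for 9 relations of quality. The arrangements within groups shuffled male and female samples apart. They did not keep the 2 samples of a dam together, so their p may be too small. A gene without any count in a group was compared with a floor of 3 counts over that group, and ratios on few counts have 95% counting intervals.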

Results

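Dorsal telencephalon of C57BL/6J fetuses was compared at gestational day 14.5 between dams exposed to ethanol vapour on gestational day 12.5 and dams exposed to control air. The 12 single-cell samples came from 6 dams, 3 per treatment, each giving 1 male and 1 female sample; the labels put the alcohol dose at 260, 250 and 210 mg/dl for alcohol dams 9, 12 and 1. The deposited files held 130029 barcodes, 7475 to 18612 per sample, with 37187001 to 87950210 unique molecular identifiers (UMIs) per sample. After filtering 94540 cells stayed, 51002 from alcohol and 43538 from control dams and 4080 to 14575 per sample. Median UMIs per kept cell ran from 2868 to 6115 in alcohol samples and from 4503 to 8432 in control samples. Median mitochondrial shares ran from 3.65% to 7.25%, so depth and mitochondrial share varied between samples.

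The shares of radial glia, intermediate progenitors, excitatory neurons and interneurons overlapped between alcohol and control dams, though 3 against 3 dams cannot show that shares are equal. The unnamed neuron-like cluster 0 held 4.63% in alcohol and 9.96% in control dams (two-sided exact p = 0.2). Radial glia, the Sox2 and Hes5 expressing progenitors of the ventricular zone, held 29.0 ± 4.12% of kept cells in alcohol dams and 27.0 ± 4.07% in control dams (mean ± SD, n = 3 and 3, two-sided exact p = 0.5). Eomes and Neurog2 expressing intermediate progenitors held 17.3 ± 3.22% and 17.2 ± 1.51% (exact p = 1). Excitatory neurons, marked by Neurod6 and Tbr1, held 35.5 ± 1.63% and 34.4 ± 0.449% (exact p = 0.4), and interneurons marked by Dlx2, Gad2 and Lhx6 held 5.41 ± 1.67% and 4.80 ± 0.768% (exact p = 0.6). Adjusted over these 4 classes the p values were 0.8, 1, 0.8 and 0.8, and the smallest p that 3 against 3 dams can give is 0.1. Among excitatory neurons, cluster 8 with Pcp4 and Rnd2 held 3.55% of the class in alcohol and 20.8% in control dams, with 38.5% of its cells from control male 3, while cluster 11 held 37.7% and 25.8%. Values for excitatory neurons below therefore compare somewhat different mixtures of clusters.

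Reln and Trp73 expressing Cajal-Retzius cells held 1.16 ± 0.445% in alcohol and 1.19 ± 0.215% in control dams (two-sided exact p = 0.9). Cldn5 positive endothelial cells held 0.268 ± 0.245% and 0.166 ± 0.0420% (exact p = 0.9), and Rgs5 positive mural cells 0.159 ± 0.113% and 0.135 ± 0.0314% (exact p = 0.9). C1qa positive microglia and macrophages held 0.428 ± 0.348% and 0.409 ± 0.0464% (exact p = 1), and erythroid cells 0.385 ± 0.270% and 0.245 ± 0.0570% (exact p = 0.6). Alcohol dam 12 held the most of the blood-borne and vascular classes, with 0.546% endothelial, 0.828% microglial and 0.696% erythroid cells. Whether the alcohol difference in a share depended on sex was tested for the 4 large classes, with exact p = 0.6, 0.3, 0.8 and 0.8 for radial glia, intermediate progenitors, excitatory neurons and interneurons.

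**Figure D1:**
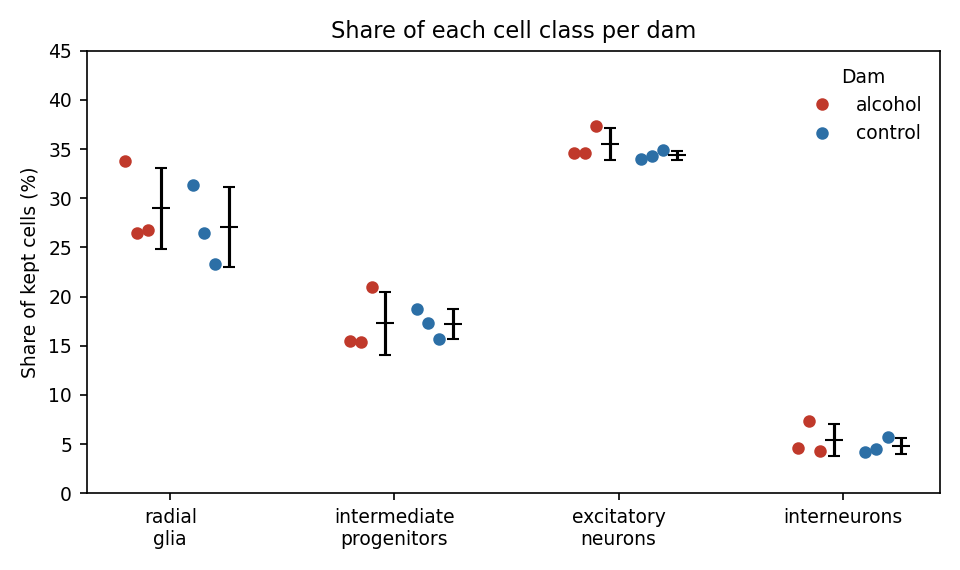
Share of kept cells in each class per dam. Radial glia held 29.0% in alcohol and 27.0% in control dams, with the spread of 3 dams per treatment shown by single points.

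In radial glia of alcohol dams the haemoglobin genes rose as a list, and genes of axon guidance and of DNA methylation and chromatin rose by small amounts. All 7 of 7 haemoglobin genes, which encode the oxygen carriers of red blood cells and are not made by radial glia, were positive with a median log2 change of 1.24 (camera adjusted p = 3.56e-13; adjusted p = 0.331 with an estimated correlation). Hbb-y (ENSMUSG00000052187, chromosome 7:103851754-103853207, mm10), the embryonic beta-like globin, stood at 363 ± 139 against 154 ± 40.5 CPM, log2 1.24 ± 0.312 (SE). Hbb-bt (ENSMUSG00000073940, chromosome 7:103812524-103813923), an adult beta globin, stood at 148 ± 70.8 against 54.2 ± 15.0, log2 1.45 ± 0.355. The alpha globins Hba-a2 (ENSMUSG00000069917, log2 1.03 ± 0.235) and Hba-a1 (ENSMUSG00000069919, log2 0.97 ± 0.254) lie side by side and have near-identical sequence, so the split between them is uncertain. Summed haemoglobin of radial glia was 183, 2685 and 80.9 CPM in alcohol males 1, 2 and 3. It was 1167, 426 and 3461 CPM in alcohol females 1, 2 and 3. Control samples ran from 196.5 to 804 CPM, above alcohol males 1 and 3, so single samples overlapped. By dam the haemoglobin score (mean log2 CPM) was 5.72, 6.48 and 6.70 in alcohol dams 9, 12 and 1. Control dams 10, 2 and 8 had 5.13, 5.06 and 5.00. Axon guidance and adhesion genes were positive in 25 of 32 with a median of 0.12 (adjusted p = 0.0082; adjusted p = 0.987 with an estimated correlation). Efna5, an ephrin ligand of growth cones, stood at log2 0.40 ± 0.232 and Efnb2 at 0.28 ± 0.184 (261 ± 9.62 against 215 ± 38.3 CPM). DNA methylation and chromatin genes were positive in 19 of 24 (adjusted p = 0.0082; adjusted p = 0.598 with an estimated correlation), Kmt2a, a histone H3 lysine 4 methyltransferase, at log2 0.30 ± 0.217. Insulin and growth factor genes were positive in 14 of 20 (adjusted p = 0.0337; adjusted p = 0.987 with an estimated correlation), with Igf2r, the receptor that clears Igf2, at log2 0.24 ± 0.145.

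No single gene of radial glia passed: edgeR called 0 of 13551 genes over all genes (smallest adjusted p = 0.999), 169 genes had unadjusted p under 0.05, and DESeq2 called 0. Adjusted over the list alone, 6 haemoglobin genes passed. Next to the haemoglobins, the smallest p among higher genes belonged to Pard3bos1, an RNA read from the strand opposite Pard3b (log2 0.94 ± 0.237, 3.33 ± 0.359 against 1.72 ± 0.364 CPM). Among lower genes it belonged to Gm29019 (−1.73 ± 0.307), followed by Mme (ENSMUSG00000027820), which encodes the membrane peptidase neprilysin (−1.06 ± 0.241, 1.60 ± 0.298 against 3.32 ± 0.551 CPM). Next came Gm47802 (−1.42), Gm48715 (−1.23) and Art1, an ADP-ribosyltransferase (−1.01 ± 0.265); none passed. The enzymes of alcohol and acetaldehyde metabolism were negative in 10 of 10 without passing as a list (adjusted p = 0.384). Aldh2, which oxidises acetaldehyde, stood at log2 −0.22 ± 0.204 (50.4 ± 7.02 against 58.6 ± 14.2 CPM) and Akr1a1 at −0.35 ± 0.256.

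In intermediate progenitors of alcohol dams haemoglobin and mitosis genes rose as lists, and immediate early and alcohol metabolism genes fell as lists, as did respiratory chain genes with control dam 2 included. Haemoglobins were positive in 6 of 6 with a median log2 change of 1.93 (adjusted p = 4.46e-10; adjusted p = 0.69 with an estimated correlation). Hbb-y stood at 410 ± 245 against 45.4 ± 13.4 CPM (log2 3.17 ± 0.514). The embryonic alpha-like globin Hba-x (ENSMUSG00000055609, chromosome 11:32276600-32278116) stood at 39.1 ± 28.4 against 4.05 ± 2.02 (3.22 ± 0.660), and Hba-a1 at 230 ± 154 against 54.6 ± 11.1 (2.07 ± 0.479). Genes of G2 and M phase were positive in 21 of 25 with a median of 0.22 (adjusted p = 0.000213; adjusted p = 0.853 with an estimated correlation). The mitotic kinesins Kif20b and Cenpe stood at 0.54 ± 0.217 and 0.48 ± 0.227. Top2a, the topoisomerase that untangles chromosomes, stood at 81.3 ± 25.5 against 57.6 ± 4.91 CPM. The G2 and M score (mean log2 CPM) of alcohol dam 1 (4.55) lay below those of control dams 2 and 8 (5.02 and 4.74), and without 1 dam the median ran from 0.12 to 0.43. Cluster 21, with Cenpe and Cdc20 among its top genes, held 11.9% of the class in alcohol and 10.3% in control dams. Nuclear genes of the respiratory chain were negative in 57 of 59 (adjusted p = 0.0155; adjusted p = 0.958 with an estimated correlation). Sdhd, an anchor of complex II, stood at −0.64 ± 0.402 and Ndufv2 of complex I at −0.49 ± 0.334. Without control dam 2 the respiratory chain median turned from −0.28 to 0.17, and without 1 of the other dams it ran from −0.54 to −0.16. Immediate early genes were negative in 11 of 13 (adjusted p = 0.046; adjusted p = 0.853 with an estimated correlation). The AP-1 subunit Junb stood at −0.90 ± 0.384 (2.54 ± 0.864 against 4.79 ± 2.14 CPM). Alcohol metabolism genes were negative in 8 of 9 (adjusted p = 0.049; adjusted p = 0.853 with an estimated correlation). The aldehyde dehydrogenase Aldh1b1 stood at −0.43 ± 0.200 (5.34 ± 1.04 against 7.22 ± 0.606 CPM), Akr1a1 at −0.40 ± 0.256 and the alcohol dehydrogenase Adh5 at −0.48 ± 0.362.

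Smaller rises in the same cells took in DNA methylation and chromatin genes (20 of 24 positive, adjusted p = 0.00347; adjusted p = 0.69 with an estimated correlation). Uhrf1, which guides Dnmt1 to new DNA, led them (0.45 ± 0.173, 36.1 ± 4.67 against 26.4 ± 4.33 CPM). They also took in axon guidance genes (24 of 31, adjusted p = 0.0155; adjusted p = 0.901 with an estimated correlation). Glutamate and GABA receptors (14 of 17, adjusted p = 0.0164; adjusted p = 0.853 with an estimated correlation) rose too, with the kainate receptor Grik1 at 0.87 ± 0.448, as did insulin and growth factor genes (15 of 18, adjusted p = 0.0476; adjusted p = 0.853 with an estimated correlation). The medians of the axon guidance, receptor and growth factor lists turned negative without control dam 2. No single gene passed: edgeR called 0 of 12632 genes over all genes, 244 genes had unadjusted p under 0.05, and DESeq2 called 2, Hbb-y and Hba-a1. Of the haemoglobin genes 5 passed adjusted over the list alone. With the median mitochondrial share as a covariate, chosen after the data were seen, 34 genes passed (15 higher, 19 lower). Other genes with small p were Gm26625 (0.98 ± 0.215), Fam209 (1.28 ± 0.291) and Fam135b (1.84 ± 0.424). On the lower side were Rab3d (ENSMUSG00000019066), a GTPase of secretory vesicles (−0.54 ± 0.127, 19.9 ± 0.509 against 28.8 ± 0.676 CPM), and Socs2 (ENSMUSG00000020027), a brake on growth hormone signalling (−0.50 ± 0.135, 35.0 ± 0.345 against 49.6 ± 5.37). The same side held the neurogenic long RNA Rmst (−0.77 ± 0.211), Cebpd (−1.38 ± 0.367), and Klf1, the erythroid transcription factor (−1.44 ± 0.384). Few cells held much of the haemoglobin in some samples: the 1% of intermediate progenitors with most haemoglobin held 74.0% of it in the median alcohol sample and 14.1% in the median control sample. In the samples of alcohol dam 9 they held 7.3% and 8.5%. Without these cells the log2 difference between alcohol and control dams was 0.70, against 1.89 with all cells (exact p = 0.2 in both).

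**Figure D2:**
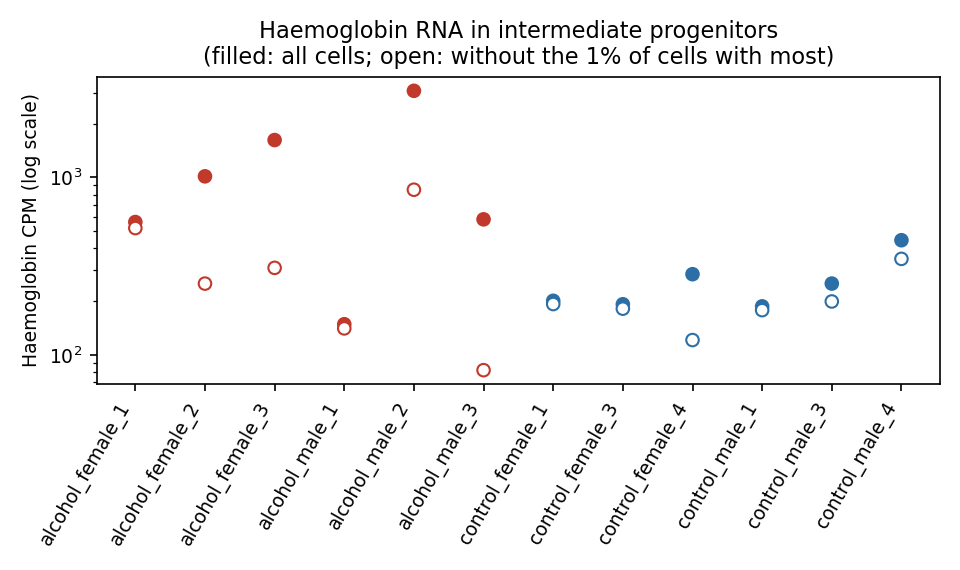
Haemoglobin RNA in intermediate progenitors of each sample, with and without the 1% of cells that hold most of it. These cells held 74.0% of it in the median alcohol and 14.1% in the median control sample.

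In excitatory neurons of alcohol dams genes of G2 and M phase rose, although these cells have left the cell cycle. All 25 of 25 were positive with a median log2 change of 0.34 (adjusted p = 5.32e-09; adjusted p = 0.694 with an estimated correlation). In males alone 13 of 25 were positive (median 0.00494, adjusted p = 0.484), and in females alone 25 of 25 (median 0.58). The score of alcohol dam 1 (2.48) lay below those of control dams 2 and 8 (2.57 and 2.70), and without 1 dam the median ran from 0.20 (alcohol dam 9 left out) to 0.54 (alcohol dam 1 left out). Cenpe (chromosome 3:135212563-135273540), the kinesin that aligns chromosomes, stood at 10.9 ± 2.86 against 6.60 ± 1.23 CPM (0.73 ± 0.234). The mitotic kinases Aurkb and Bub1 stood at 0.64 ± 0.267 and 0.65 ± 0.275, and Kif23 at 0.54 ± 0.232. Radial glia markers outside the cell cycle stood above 0 in the same neurons in 9 of 13 cases, among them Nes (0.52 ± 0.245) and Hes1 (0.39 ± 0.404). Vim (−0.44 ± 0.438), Fabp7 (−0.25 ± 0.423), Dbi (−0.10 ± 0.309) and Ptprz1 (−0.09 ± 0.187) stood below 0. None of these markers passed, and the SE of Hes1 and of the markers below 0 was near or above the change. Haemoglobins were positive in 7 of 7 (adjusted p = 0.0094; adjusted p = 0.694 with an estimated correlation), Hba-a1 at 186 ± 116 against 99.4 ± 22.3 CPM. DNA methylation and chromatin genes were positive in 19 of 24 (adjusted p = 0.0094; adjusted p = 0.694 with an estimated correlation), with Dnmt3a, the de novo methyltransferase, at 0.24 ± 0.131. Axon guidance genes were positive in 26 of 33 (adjusted p = 0.0255; adjusted p = 0.815 with an estimated correlation), though their median turned negative without control dam 2. Immediate early genes fell as a list, with 9 of 13 negative (adjusted p = 0.0255; adjusted p = 0.694 with an estimated correlation). Ier3 stood at 5.57 ± 0.978 against 7.77 ± 0.705 CPM (−0.48 ± 0.183) and Junb at −0.67 ± 0.317.

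No single gene of excitatory neurons passed: edgeR called 0 of 14157 genes over all genes, 242 had unadjusted p under 0.05, DESeq2 called 0, and adjusted over the list alone 0 G2 and M genes passed. Genes with small p and higher values included Sparc (ENSMUSG00000018593), a matrix glycoprotein of glia and vessels (0.88 ± 0.206, 2.27 ± 0.299 against 1.23 ± 0.117 CPM), and the mitotic kinesin Kif18b (ENSMUSG00000051378, 1.04 ± 0.254, 0.815 ± 0.0407 against 0.384 ± 0.0705). The histone gene Hist2h2ac (1.23 ± 0.326), Gm26691 (1.38) and 1700080N15Rik (1.03) followed. Lower values were found for Slit3 (ENSMUSG00000056427, chromosome 11:35121456-35708507), a secreted axon repellent (−0.84 ± 0.213, 6.67 ± 1.02 against 11.9 ± 2.95 CPM), and Mical2 (ENSMUSG00000038244), an actin oxidase downstream of semaphorins (−0.88 ± 0.182, 2.11 ± 0.209 against 3.86 ± 0.373). Adra2c (ENSMUSG00000045318), the alpha-2C adrenergic receptor (−0.70 ± 0.178, 8.31 ± 0.898 against 13.4 ± 2.40), 4930589L23Rik (−1.20) and Gm9903 (−1.47) were lower too. Alcohol metabolism genes were negative in 8 of 10 (adjusted p = 0.0778) and S phase genes gave adjusted p = 0.0877; neither list passed. With the median mitochondrial share as a covariate, an alternative chosen after the data were seen, 153 genes passed, 43 higher and 110 lower, while the other divisions of the dams gave at most 1. They included Etv1 (1.64 ± 0.236, adjusted p = 0.00972), Lin28b (0.74 ± 0.125), and lower Cck (−0.86 ± 0.11, adjusted p = 0.00578), Crym (−0.94 ± 0.126) and Adra2c (−0.71 ± 0.128, adjusted p = 0.0357). Tsix, an RNA higher in females than in males, was among the higher genes too (0.77 ± 0.141, adjusted p = 0.0357). Female samples held more of the UMIs in alcohol dams.

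**Figure D3:**
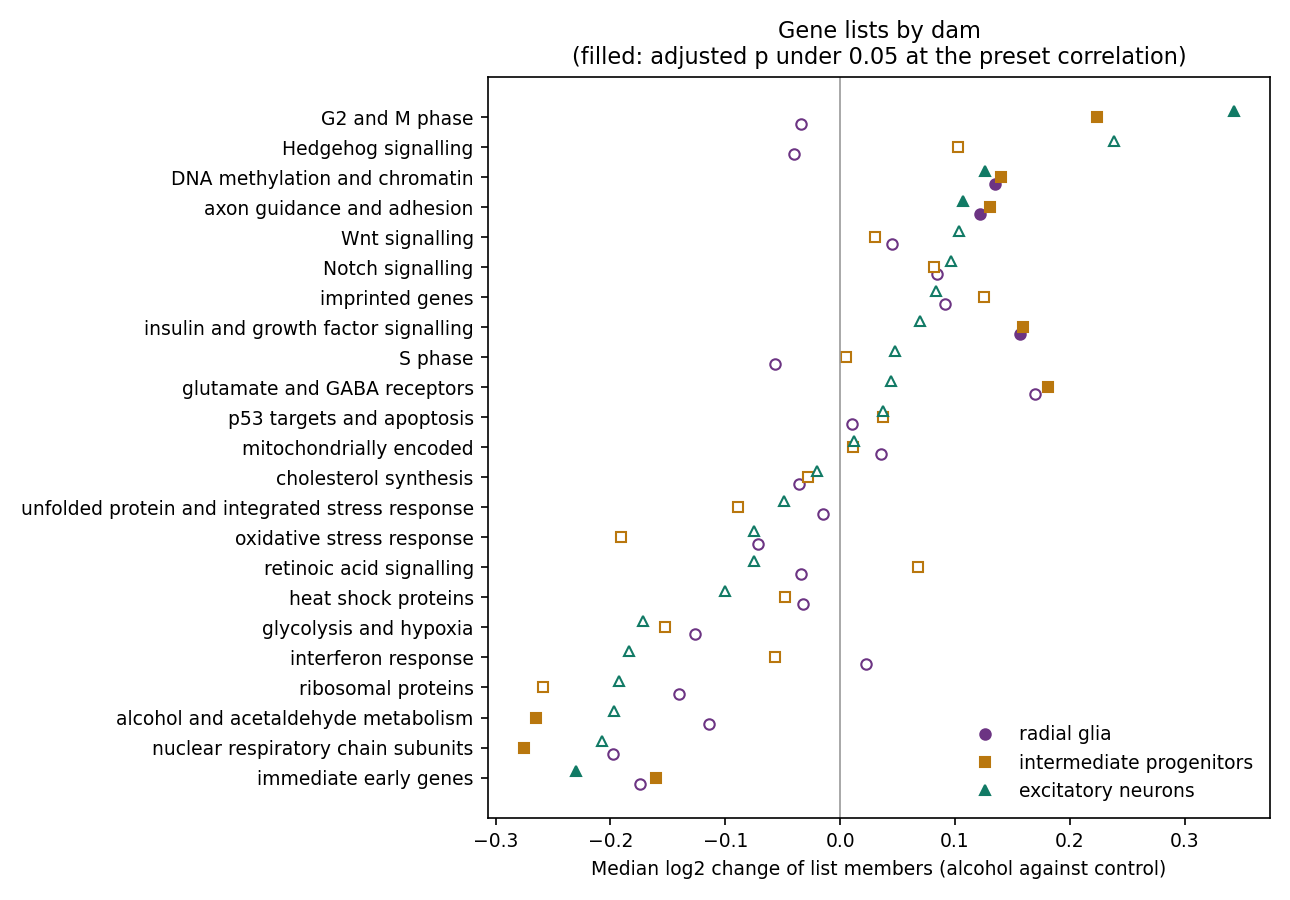
Median log2 change of each gene list by dam in the 3 large classes. Genes of G2 and M phase stood at 0.34 in excitatory neurons, and haemoglobins, at 1.93 in intermediate progenitors, lie beyond the axis and are left out.

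Interneurons of alcohol dams showed higher mitosis and Hedgehog genes as lists. Genes of G2 and M phase were positive in 20 of 22 with a median of 0.24 (adjusted p = 3.52e-08; adjusted p = 0.353 with an estimated correlation). The G2 and M score was 3.67, 4.04 and 3.44 in males of alcohol dams 9, 12 and 1. In males of control dams 10, 2 and 8 it was 3.23, 3.88 and 4.05, so the male values overlapped. In females of the same dams it was 4.34, 4.08 and 3.83 against 3.55, 3.83 and 3.45. Hedgehog genes were positive in 6 of 7 with a median of 0.34 (adjusted p = 0.00337; adjusted p = 0.353 with an estimated correlation). DNA methylation and chromatin genes were positive in 22 of 24 (adjusted p = 0.00337; adjusted p = 0.353 with an estimated correlation). Haemoglobins (6 of 6, adjusted p = 0.00625; adjusted p = 0.771 with an estimated correlation) and insulin and growth factor genes (11 of 16, adjusted p = 0.0211; adjusted p = 0.353 with an estimated correlation) also rose. The haemoglobin median turned slightly negative without alcohol dam 12. Immediate early genes fell (7 of 9 negative, adjusted p = 0.0499; adjusted p = 0.89 with an estimated correlation). For single genes edgeR called 0 of 10538 (237 at unadjusted p under 0.05; DESeq2 0), so the following values did not pass. Pold1, the catalytic subunit of DNA polymerase delta, stood at 19.4 ± 0.297 against 10.9 ± 2.06 CPM (0.84 ± 0.213), the cadherin Fat4 at 0.96 ± 0.267 and Phf13 at 1.13 ± 0.327. Btd (−1.25 ± 0.304), Abt1 (−0.84 ± 0.213) and the adhesion molecule Sdk1 (−1.20 ± 0.312) were lower. Another division of the dams, with 9, 10 and 1 on the same side, called 227 interneuron genes, which points to a structure of the samples other than treatment. The median mitochondrial share of interneurons was 7.13%, 7.10% and 6.31% in males of these dams. It was 5.09%, 4.56% and 5.23% in males of dams 12, 2 and 8. In females it was 5.64%, 7.89% and 5.54% against 4.95%, 4.90% and 5.74%.

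With all cells of a dam summed, the endothelial genes Tie1 and Vwf stood higher in alcohol dams; a list of vessel genes was not tested. Tie1 (ENSMUSG00000033191, chromosome 4:118471191-118489849), an endothelial receptor kinase, stood at 1.62 ± 0.639 against 0.522 ± 0.0394 CPM (1.63 ± 0.308). Vwf (ENSMUSG00000001930), the endothelial clotting factor, stood at 1.92 ± 0.883 against 0.552 ± 0.156 and the vasodilator gene Adm at 1.42 ± 0.299. Only DESeq2 called Tie1 and Vwf, its 2 genes. From edgeR came 0 of 16297 genes, with 316 at unadjusted p under 0.05. Endothelial cells held 0.268% of the cells in alcohol and 0.166% in control dams. The share was 0.1754%, 0.5455% and 0.0837% in alcohol dams 9, 12 and 1. It was 0.1182%, 0.1855% and 0.1955% in control dams 10, 2 and 8, so only alcohol dam 12 lay above the control dams. Slit3 (−0.87 ± 0.216, 3.25 ± 0.408 against 5.93 ± 1.5 CPM), Dmrtc1a (−1.07) and Klrk1 (−1.0) stood lower without passing. As lists, haemoglobins (7 of 7 positive, median 0.77, adjusted p = 0.00535; adjusted p = 0.772 with an estimated correlation) and insulin and growth factor genes (18 of 21, adjusted p = 0.0139; adjusted p = 0.933 with an estimated correlation) rose. So did DNA methylation and chromatin genes (19 of 24, adjusted p = 0.0139; adjusted p = 0.772 with an estimated correlation) and axon guidance genes (27 of 33, adjusted p = 0.0342; adjusted p = 0.933 with an estimated correlation). The axon guidance median turned negative without control dam 2. Imprinted genes rose (17 of 24 positive, adjusted p = 0.0139; adjusted p = 0.772 with an estimated correlation). The growth-limiting long RNA H19 stood at 6.63 ± 1.49 against 4.31 ± 1.06 CPM. Immediate early genes fell (11 of 14 negative, adjusted p = 0.0264; adjusted p = 0.933 with an estimated correlation). Adm was the only glycolysis and hypoxia gene to pass adjusted over the list alone.

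List medians were recomputed with each replicate left out, an alternative chosen after the list results had been seen. Of 68 lists that passed by dam, in males or in females, 12 turned direction and 64 turned or moved by more than 1.5 times without 1 replicate. Without control dam 2 axon guidance medians became −0.05 in all cells, −0.08 in radial glia, −0.06 in intermediate progenitors and −0.04 in excitatory neurons. In intermediate progenitors those of insulin and growth factor genes became −0.01 and those of glutamate and GABA receptors −0.03. Without alcohol dam 9 the immediate early median became 0.01 in excitatory neurons, and without alcohol male 1 it became 0.01 in intermediate progenitors of males. Without alcohol dam 12 the haemoglobin median of interneurons went from 1.48 to −0.01. The ribosomal median of radial glia of females (−0.01) ran from −0.33 to 0.59.

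Stress and death genes did not pass as lists in the by-dam comparisons, and of the patterning lists only Hedgehog genes did, in interneurons. In radial glia, oxidative stress genes were negative in 14 of 19 (adjusted p = 0.884), unfolded protein and integrated stress response genes in 10 of 19 (adjusted p = 0.905). The p53 targets and apoptosis genes were positive in 8 of 16 (adjusted p = 0.837). Heat shock proteins gave adjusted p = 0.801, interferon response genes 0.801, glycolysis and hypoxia genes 0.905 with 16 of 24 negative, and cholesterol synthesis genes 0.801. Notch genes gave 0.837, Wnt genes 0.884, Hedgehog genes 0.966 and retinoic acid genes 0.801. S phase genes were negative in 17 of 25 (adjusted p = 0.801) and G2 and M genes in 15 of 25 (adjusted p = 0.801). Nuclear respiratory chain genes were negative in 55 of 59 (adjusted p = 0.292), ribosomal protein genes in 67 of 80 (adjusted p = 0.884), and mitochondrially encoded genes gave adjusted p = 0.526. Glutamate and GABA receptors (adjusted p = 0.147), imprinted genes (0.175) and immediate early genes (0.175) did not pass either in radial glia.

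Male samples of alcohol dams had lower ribosomal protein and nuclear respiratory chain genes and higher mitochondrially encoded genes than male samples of control dams, in each of the 3 large classes. Ribosomal protein genes were negative in 78 of 80 in radial glia (median log2 −0.38, adjusted p = 3.44e-05), 79 of 80 in intermediate progenitors (−0.49, adjusted p = 8.17e-08) and 80 of 80 in excitatory neurons (−0.47, adjusted p = 1.79e-07). In the same order they had adjusted p = 0.83, 0.732 and 0.808 with an estimated correlation. Rps13 of the small subunit stood at 524 ± 223 against 968 ± 586 CPM in excitatory neurons (−0.88 ± 0.478, n = 3 and 3). Nuclear respiratory chain genes were negative in 59 of 59 in radial glia (−0.46, adjusted p = 2.86e-08), 58 of 59 in intermediate progenitors (−0.53, adjusted p = 4.19e-09) and 58 of 59 in excitatory neurons (−0.50, adjusted p = 4.94e-08). They had adjusted p = 0.83, 0.669 and 0.807 with an estimated correlation. Cox5a of complex IV stood at −1.02 ± 0.440 and Uqcrb of complex III at −0.97 ± 0.398 in intermediate progenitors. Mitochondrially encoded genes were positive in 13 of 13 in radial glia (0.21, adjusted p = 0.00384), 11 of 13 in intermediate progenitors (adjusted p = 0.017) and 11 of 13 in excitatory neurons (adjusted p = 0.0184). Their values were adjusted p = 0.83, 0.669 and 0.807 with an estimated correlation. The median mitochondrial share of excitatory neurons was 7.45%, 5.03% and 6.34% in the alcohol males and 7.14%, 4.02% and 5.45% in the control males. Their median UMIs per cell were 5035, 5268 and 5444 in the alcohol males and 6667, 9480 and 6039 in the control males. With the median mitochondrial share as a covariate, chosen after the data were seen, the ribosomal medians of males were 0.12, −0.05 and −0.09 and the respiratory chain medians −0.04, −0.17 and −0.14 in radial glia, intermediate progenitors and excitatory neurons. Without control male 3 they were 0.04, −0.08 and −0.06 for ribosomal and −0.11, −0.16 and −0.11 for respiratory chain genes, in the same order and without the covariate.

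Axon guidance genes rose in males of alcohol dams in radial glia (26 of 30, adjusted p = 0.000252), intermediate progenitors (30 of 31, adjusted p = 2.78e-05) and excitatory neurons (30 of 33, adjusted p = 0.00137). This list had adjusted p = 0.83, 0.669 and 0.807 with an estimated correlation. Efna5 stood at 0.88 ± 0.320 and the neurite adhesion gene L1cam at 154 ± 33.3 against 107 ± 33.8 CPM (0.53 ± 0.258) in intermediate progenitors. DNA methylation and chromatin genes rose in the same classes (adjusted p = 0.0225, 0.00986 and 0.0133; adjusted p = 0.83, 0.669 and 0.807 with an estimated correlation). The histone methyltransferase gene Kmt2d stood at 0.66 ± 0.228 in intermediate progenitors. Insulin and growth factor genes rose in radial glia (16 of 19, adjusted p = 0.00281; adjusted p = 0.83 with an estimated correlation) and intermediate progenitors (13 of 16, adjusted p = 0.0219; adjusted p = 0.669 with an estimated correlation). Alcohol metabolism genes fell in excitatory neurons, with 9 of 9 negative (adjusted p = 0.00859; adjusted p = 0.807 with an estimated correlation). Adh5 stood at −0.78 ± 0.360, Akr1a1 at −0.63 ± 0.260 and Aldh1b1 at −0.43 ± 0.188. Immediate early genes fell in excitatory neurons (11 of 13, adjusted p = 0.00814; adjusted p = 0.807 with an estimated correlation; Junb −1.08 ± 0.337) and intermediate progenitors (adjusted p = 0.0222; adjusted p = 0.669 with an estimated correlation). Heat shock genes fell in excitatory neurons (10 of 11, adjusted p = 0.0401; adjusted p = 0.807 with an estimated correlation). In intermediate progenitors oxidative stress genes (15 of 18 negative, adjusted p = 0.0276; adjusted p = 0.669 with an estimated correlation) fell, with the peroxidase Prdx1 at −0.87 ± 0.366. Glycolysis and hypoxia genes fell there too (15 of 23, adjusted p = 0.0454; adjusted p = 0.669 with an estimated correlation; Pgk1 −0.71 ± 0.253). Glutamate and GABA receptors (11 of 14, adjusted p = 0.0158; adjusted p = 0.669 with an estimated correlation) and haemoglobins (6 of 6, adjusted p = 0.0353; adjusted p = 0.669 with an estimated correlation) rose there. The haemoglobin score (mean log2 CPM) was 4.33, 8.72 and 6.42 in alcohol males 1, 2 and 3. It was 4.53, 5.34 and 5.86 in control males 1, 3 and 4, so alcohol male 1 lay below every control male. Among the haemoglobins 4 genes passed adjusted over the list alone. The median mitochondrial share of intermediate progenitors was 5.92 ± 1.15% in alcohol males and 5.14 ± 1.36% in control males (mean ± SD). Medians with this share as covariate were not computed for the lists of this paragraph other than haemoglobins.

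No single gene passed in males: edgeR called 0 of 12344 genes in radial glia, 0 of 11526 in intermediate progenitors and 0 of 13043 in excitatory neurons. At unadjusted p under 0.05 there were 465, 755 and 531 genes, and DESeq2 called 0 in each. In radial glia, Slc13a3, a dicarboxylate carrier (1.86 ± 0.430), Gm40841 (1.24) and Samd5 (1.00 ± 0.258) were highest by p, and the histone gene Hist2h4 (−1.77 ± 0.382), the tendon factor Scx (−2.32 ± 0.519) and 9430060I03Rik (−2.32) lowest. In intermediate progenitors these places went to Nrxn3, a presynaptic neurexin (1.26 ± 0.308, 11.2 ± 3.56 against 4.69 ± 1.41 CPM), Ahdc1 (0.70 ± 0.175) and Syne4 (1.47), and on the lower side to Arxes1 (−0.88 ± 0.206), the opioid precursor Penk (−1.43 ± 0.364) and Hist4h4 (−1.12). In excitatory neurons they went to Dok3, an adaptor of immune receptors (1.24 ± 0.218, 5.48 ± 0.758 against 2.30 ± 0.152 CPM), Cfp (0.92 ± 0.209), 1700102P08Rik (1.20), C130013H08Rik (−1.21), Gm26766 (−1.60) and Gm14167 (−1.72). Without control male 1 intermediate progenitors gave 497 genes. A division with dams 9, 10 and 1 on the same side gave 677 genes in intermediate progenitors and 1032 in excitatory neurons, which points to a structure of the samples other than treatment. In males of these dams the median mitochondrial share of excitatory neurons was 7.45%, 7.14% and 6.34%. It was 5.03%, 4.02% and 5.45% in dams 12, 2 and 8, so this division also parted the males by mitochondrial share. On the first principal component dams 9, 10 and 1 lay below 0 and the others above 0.

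Female samples of alcohol dams had higher mitosis and haemoglobin genes than female samples of control dams. Genes of G2 and M phase were positive in 25 of 25 in excitatory neurons (median 0.58, adjusted p = 1.56e-23) and in 24 of 25 in intermediate progenitors (0.34, adjusted p = 1.13e-11). With these lists came adjusted p = 0.585 and 0.707 with an estimated correlation. In the neurons Hmmr, a spindle-binding receptor, stood at 3.42 ± 0.840 against 1.58 ± 0.366 CPM, Aurkb at 1.01 ± 0.304, Kif11 at 0.82 ± 0.30 and Top2a at 0.79 ± 0.30. In intermediate progenitors Top2a stood at 92.3 ± 22.9 against 57.7 ± 6.53 CPM. S phase genes rose in intermediate progenitors (18 of 25, adjusted p = 0.0043; adjusted p = 0.856 with an estimated correlation) and excitatory neurons (17 of 25, adjusted p = 0.0183; adjusted p = 0.727 with an estimated correlation). Cdc6, which loads the replication helicase, stood at 0.92 ± 0.370 in the neurons. Haemoglobins were positive in 6 of 6 in intermediate progenitors (median 1.98, adjusted p = 6.54e-19), 6 of 6 in radial glia (1.23, adjusted p = 0.00987) and 4 of 6 in excitatory neurons (0.67, adjusted p = 0.00381). The haemoglobins had adjusted p = 0.116, 0.9 and 0.609 with an estimated correlation in this order. Adjusted over the list alone, 6 haemoglobin genes passed in intermediate progenitors and 2 in excitatory neurons.

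Notch genes rose in female excitatory neurons (11 of 14, adjusted p = 0.0375; adjusted p = 0.609 with an estimated correlation), with the effector Hes5 at 0.41 ± 0.272. Hes5 and Hes1 are radial glia markers too, and 10 of 13 such markers outside the cell cycle stood above 0 in these neurons (median 0.17), among them Sox2 (0.59 ± 0.34), Nes (0.45 ± 0.254) and Hes1 (0.52 ± 0.473), without passing. Vim (−0.21 ± 0.491), Ptprz1 (−0.19 ± 0.231) and Slc1a3 (−0.06 ± 0.231) stood below 0. Retinoic acid genes fell (8 of 11, adjusted p = 0.0397; adjusted p = 0.585 with an estimated correlation), with the nuclear receptor Nr2f2 at 13.4 ± 4.13 against 24.3 ± 5.82 CPM. DNA methylation and chromatin genes rose in radial glia, intermediate progenitors and excitatory neurons (adjusted p = 0.011, 0.0335 and 0.0181; adjusted p = 0.9, 0.707 and 0.585 with an estimated correlation). Uhrf1 stood at 0.51 ± 0.193 in intermediate progenitors. Ribosomal protein genes of radial glia ranked up against other genes (adjusted p = 0.011; adjusted p = 0.9 with an estimated correlation) although 45 of 80 were negative. With the median mitochondrial share as a covariate the ribosomal medians of females were −0.18 in radial glia, −0.30 in intermediate progenitors and −0.38 in excitatory neurons. No single gene passed: edgeR called 0 of 12860 genes in radial glia, 0 of 11688 in intermediate progenitors and 0 of 13306 in excitatory neurons. At unadjusted p under 0.05 there were 103, 152 and 196. DESeq2 called 0 genes, 2 genes (Hba-a1 and Hba-a2, 2.12 ± 0.323 for Hba-a1, 202 ± 90.2 against 46.3 ± 2.87 CPM) and 1 gene (Hbb-y, 3.97 ± 0.722, 331 ± 239 against 21.1 ± 13.2 CPM). Other genes with small p were Pard3bos1 (1.26), Gpd1 (1.60 ± 0.420), Phykpl (0.96 ± 0.257), the dynein chain Dync1i1 (−1.15), Art1 and Ptpn3 (−1.06) in radial glia. In intermediate progenitors they were Gm26625 (1.55), Thrsp (−1.58), Gsap (−0.76 ± 0.199) and Gm6297 (−1.14), and in excitatory neurons Hist2h2ac (2.13), Wwtr1 (1.07 ± 0.246), Gm31816 (−1.39), Efcab1 (−1.71) and Gpr162 (−0.58 ± 0.152). With the median mitochondrial share as a covariate, chosen after the data were seen, 1154 genes passed in intermediate progenitors and 3436 in excitatory neurons, against at most 4 and 1 for other divisions of the dams. The covariate stood at 5.18 ± 0.477% in alcohol and 6.17 ± 1.73% in control females in excitatory neurons.

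The alcohol difference was compared between the sexes, and without dam as block no gene passed. The edgeR 4-group model called 0 of 12950 genes in radial glia, 0 of 12003 in intermediate progenitors and 0 of 13695 in excitatory neurons (115, 120 and 94 at unadjusted p under 0.05; DESeq2 called 0 in each). Genes with small p, none of which passed, were Slc13a3, Csgalnact1 (1.76), Zfp551 (1.37), 9330121J05Rik (−1.58), Hist2h4 (−1.91) and the dopamine receptor Drd4 (−1.25) in radial glia. In intermediate progenitors they were Gm27008 (1.37), Gm43625 (2.96), the enolase Eno3 (1.03 ± 0.311), 4833418N02Rik (−1.02), Cyp39a1, an oxysterol hydroxylase (−0.86 ± 0.260), and D830025C05Rik (−2.18). In excitatory neurons they were Insl5 (1.96), Gm48935 (2.07), 1700102P08Rik (0.95), Efcab11 (−1.26), Hbb-bh1 (−4.67 ± 1.45) and Klhl13 (−0.74 ± 0.234).

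With dam as block, an alternative chosen before the data were examined that pairs the male and female sample of each dam, ribosomal and respiratory genes were lower in males than in females of alcohol dams relative to control dams. The block gave 396 genes in intermediate progenitors (74 higher, 322 lower), 694 in excitatory neurons (577 of them lower) and 0 in radial glia. Of these genes of the block 298 were shared by the first 2 classes, which come from the same samples. In intermediate progenitors Uqcrb (chromosome 13:66900576-66905350) of complex III stood at −0.96 ± 0.137 (adjusted p = 0.00494 with the block), and Cox5a (chromosome 9:57517328-57532427) at −0.85 ± 0.130. With the block the RNA polymerase subunit Polr2k stood at −0.79 ± 0.120, Mif at −0.78 ± 0.122 and Rps13 at −0.86 ± 0.136. Higher genes with the block included the semaphorin receptor Nrp1 (0.55 ± 0.119), Fbxl19 (0.65 ± 0.140) and Gm42418, which overlaps 45S ribosomal RNA (0.78 ± 0.169). In excitatory neurons 80 of 80 ribosomal protein genes were negative with the block (median −0.54, adjusted p = 1.45e-28; adjusted p = 0.49 with an estimated correlation). Of them 58 passed over all genes and 76 adjusted over the list alone. Their male-minus-female log2 difference was −0.407 ± 0.144 in alcohol dams and 0.112 ± 0.194 in control dams (mean ± SD, n = 3 and 3 dams, paired by the block).

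The same block put 59 of 59 nuclear respiratory chain genes below 0 in excitatory neurons (median −0.52, adjusted p = 1.46e-23; adjusted p = 0.49 with an estimated correlation). Of these, 38 passed over all genes with the block and 53 adjusted over the list alone. Mitochondrially encoded genes were above 0 in 13 of 13 with the block (0.31, adjusted p = 0.000164; adjusted p = 0.49 with an estimated correlation). In intermediate progenitors the block gave 80 of 80 ribosomal protein genes below 0 (−0.51, adjusted p = 5.85e-26; adjusted p = 0.374 with an estimated correlation) and 31 called respiratory chain genes. In radial glia, where no single gene passed, the block put 80 of 80 ribosomal protein genes (median −0.49, adjusted p = 7.91e-21) and 58 of 59 nuclear respiratory chain genes (−0.51, adjusted p = 1.11e-23) below 0, both with adjusted p = 0.604 with an estimated correlation. G2 and M genes were lower in intermediate progenitors with the block (22 of 25, adjusted p = 0.000192; adjusted p = 0.459 with an estimated correlation). They were lower with the block in excitatory neurons too (24 of 25, median −0.66, adjusted p = 0.00111; adjusted p = 0.748 with an estimated correlation). Their male-minus-female log2 difference in intermediate progenitors was −0.446 ± 0.123 in alcohol and −0.00977 ± 0.374 in control dams. In excitatory neurons it was −0.318 ± 0.121 and 0.214 ± 0.672. Only in control dam 8 did the male G2 and M score lie above the female one. It was 4.95 against 4.54 in intermediate progenitors and 3.12 against 2.14 in excitatory neurons. Axon guidance genes were higher with the block in intermediate progenitors, 29 of 31 (median 0.33, adjusted p = 1.8e-07; adjusted p = 0.193 with an estimated correlation), with L1cam and Nrp1 among those of smallest p. They were the only list past fry with the block (adjusted p = 0.0336), and 4 passed over all genes and 13 adjusted over the list alone. Immediate early genes of excitatory neurons were lower with the block (12 of 13, adjusted p = 0.00196; adjusted p = 0.49 with an estimated correlation). Excitatory neurons of males had a larger mitochondrial share than those of females in each alcohol dam (by 1.94, 0.394 and 0.946 percentage points in dams 9, 12 and 1). The share was smaller in males in each control dam (by 0.694, 0.357 and 0.833 points in dams 10, 2 and 8). Over the 6 dams the male-minus-female ribosomal protein score followed that of the mitochondrial share with Pearson r = −0.953 (Spearman rho = −1.0, exact p = 0.00278, Benjamini-Hochberg 0.00833 over 6 relations; r = −0.928 without the 2 farthest dams). With the mitochondrial share added to the block 0 genes passed. The median change of the lower genes of excitatory neurons moved from −0.540 to −0.305. The median SE of a single gene, over all 694 genes of the block, moved from 0.120 to 0.22. Leaving out control dam 8 left 0 genes with the block in both classes, and leaving out control dam 10 left 0 and 5. Without alcohol dam 9 the block gave 128 genes in intermediate progenitors and 142 in excitatory neurons, without alcohol dam 12 330 and 568, without alcohol dam 1 506 and 849, and without control dam 2 931 and 1046.

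**Figure D4:**
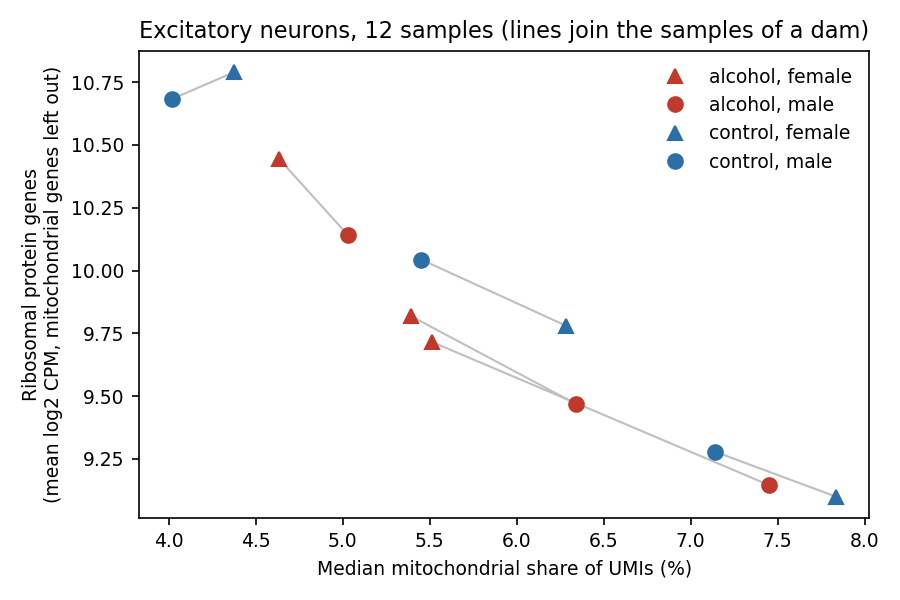
Ribosomal protein score against median mitochondrial share in excitatory neurons, by sample. Within groups Pearson r was −0.987 (exact p = 0.000772, Benjamini-Hochberg 0.00231 over 9 relations) and −0.977 without the 2 farthest samples. Spearman rho was −0.979 over all samples. The permutation did not keep the 2 samples of a dam together, so its p may be too small.

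The genes that edgeR called between male and female samples lie on the X and Y chromosomes. In all cells edgeR called 7 of 15663 genes, 5 higher in males and 2 lower (332 at unadjusted p under 0.05). Kdm5d (ENSMUSG00000056673, chromosome Y:897566-943813), a histone H3 lysine 4 demethylase, stood at 60.9 ± 9.30 CPM in males (n = 6, adjusted p = 7.27e-12). Uty (ENSMUSG00000068457), a relative of the histone H3 lysine 27 demethylases, stood at 64.9 ± 16.5 CPM (adjusted p = 5.77e-10). Kdm5d had 1 count over all females, a male to female ratio of 16539 (95% counting interval 2968 to 653308). Ddx3y (ENSMUSG00000069045), an RNA helicase gene (70.8 ± 7.86 CPM, adjusted p = 5.62e-08), and Eif2s3y (ENSMUSG00000069049), a translation initiation factor (130 ± 23.8 CPM, adjusted p = 5.10e-07), had 0 counts in females. Against a floor of 3 counts they were at least 6482-fold and 12203-fold higher in males, and Gm29650, the remaining gene, at least 511-fold. The 95% counting intervals of these ratios begin lower, at 5271, 9924 and 415. Xist (ENSMUSG00000086503, chromosome X:103460373-103483233), the RNA that silences 1 X chromosome, stood at 2346 ± 592 CPM in females and 0.260 ± 0.0729 in males (−13.2 ± 0.325, adjusted p = 7.09e-11). Tsix (ENSMUSG00000085715), its antisense partner, stood at 56.9 ± 19.8 and 0.0608 CPM (−9.95 ± 0.364, adjusted p = 4.93e-09). The pair overlaps on opposite strands, so part of the Tsix signal may be Xist reads. No autosomal gene was called by edgeR: Ddit4l, an inhibitor of mTOR (−0.57 ± 0.122, adjusted p = 0.784), Fndc1 (2.00), and Flt4, a lymphatic receptor (1.27 ± 0.312), had small p. So had Btbd18 (−1.15) and Nog, an inhibitor of bone morphogenetic proteins (−0.35 ± 0.0878, 8.25 ± 0.790 against 10.5 ± 0.620 CPM). DESeq2 called 9 genes, adding Ddit4l (adjusted p = 0.00536) and Gm28587. With dam as block 9 passed, adding the X genes Kdm6a (−0.53, adjusted p = 0.00201) and Eif2s3x (−0.52, adjusted p = 0.00564), which escape X inactivation.

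In Cajal-Retzius, erythroid and microglial cells no gene passed by dam: edgeR called 0 of 9376, 0 of 3404 and 0 of 6015 genes, with 220, 268 and 73 at unadjusted p under 0.05, and DESeq2 called 0 in each. Endothelial and mural cells had fewer than 20 kept cells in at least 1 dam and were not analysed here for gene changes. Without alcohol dam 12 erythroid cells gave 4 genes, and without alcohol dam 9 microglia gave 8. Another division of the dams, with 9, 1 and 8 on the same side, gave 26 genes in microglia, which points to a structure of the samples.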

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

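The tests of explanations and the divisions of the dams and samples below were chosen only after the results had been seen, except the test of radial glia markers in excitatory neurons; dam as block was chosen before the data were examined.

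With dam as block 396 genes of intermediate progenitors and 694 of excitatory neurons passed in a test of whether the alcohol difference differed between the sexes. Without the block 0 genes passed in these classes. With the block, leaving out control dam 8 left 0 genes in both classes, and leaving out control dam 10 left 0 and 5. No gene passed with the mitochondrial share added to the block. Among the gene lists ribosomal proteins had the smallest camera p on the lower side in both classes. Among single genes Uqcrb, Polr2k, Nop10 and Cox5a had the smallest p on the lower side in intermediate progenitors. Within groups the ribosomal protein score in excitatory neurons fell as the mitochondrial share rose (Pearson r = −0.987, exact p = 0.000772, Benjamini-Hochberg 0.00231 over 9 relations; over all samples r = −0.960 and Spearman rho = −0.979; −0.977 without the 2 farthest samples). The permutations within groups did not keep the 2 samples of a dam together, so their p may be too small. A difference in cell or RNA quality between paired samples could give such a relation of the score with the mitochondrial share. Sequencing depth could not be judged: within groups the same score rose with depth (r = 0.727, exact p = 0.0162, Benjamini-Hochberg 0.0182 over 9 relations; over all samples r = 0.637 and rho = 0.587; 0.809 without the 2 farthest samples), while over the 6 dams the male-minus-female score against depth gave r = −0.290 (rho = −0.314, exact p = 0.578, Benjamini-Hochberg 0.693 over 6 relations; −0.147 without the 2 farthest dams). As many genes with the block came from 1 of 10 divisions of the dams in intermediate progenitors and 1 of 10 in excitatory neurons, the real one (other divisions at most 2 and 2), and from 10 of 10 in radial glia (real 0, highest other 1), and 10 are too few for a share under 0.05. A response of male and female fetuses to alcohol that differs in translation and respiration stays open, since quality and biology were not separated by any test here.

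Haemoglobin RNA was higher in intermediate progenitors of alcohol dams, a pattern that cells of the erythroid line could bring in. A few cells with very high haemoglobin may account for most of it: the 1% of cells with most held 74.0% in the median alcohol sample, a test set up after the same share over all 12 samples had given a median of 22.0%. In alcohol dam 9 they held 7.3% and 8.5%. In radial glia the 1% of cells with most held 7.8% to 91.8% in alcohol and 5.8% to 82.8% in control samples. In excitatory neurons they held 50.7% to 80.7% and 4.8% to 78.7%, so the values of the treatments overlapped widely in these classes. Free RNA of blood cells could not be judged. In intermediate progenitors a log2 difference of 0.70 was left without the 1% of cells with most (exact p = 0.2) out of 1.89 with all cells (exact p = 0.2 as well). The share of erythroid cells could not be judged either (within groups r = 0.75, exact p = 0.227, a single relation; over all samples r = 0.685 and rho = 0.399; 0.698 without the 2 farthest samples). Whether alcohol raises the number of fetal red cells in the tissue was not tested.

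Genes of G2 and M phase were higher as a list in excitatory neurons of alcohol dams, with 25 of 25 positive in females alone and 13 of 25 in males alone, and with the score of alcohol dam 1 (2.48) below those of control dams 2 and 8 (2.57 and 2.70). The radial glia RNA explanation was tested with radial glia markers outside the cell cycle, whose median log2 change in the same neurons was 0.20, against 0.34 for the G2 and M genes. Radial glia RNA or cells among the neurons could give such a rise. Not all markers rose: Vim (−0.44), Fabp7 (−0.25), Dbi (−0.10) and Ptprz1 (−0.09) stood below 0, and no marker passed. Over the 6 dams the 2 scores moved together (r = 0.957, rho = 0.943, exact p = 0.00278, a single relation; 0.862 without the 2 farthest dams). Whether neurons of alcohol dams leave the cell cycle late was not tested.

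Among the genes named for the comparison of the sexes, some of them picked by small p, 3 of 22 groups of 6 samples had a sample far from the others, where chance gives about 1 in 20 for genes not so picked. Kdm5d in alcohol female 2 held 0.0171 CPM, which is 1 count, against 0 in the other females, so its gap over range is 1 by construction. Flt4 in alcohol male 2 held 1.91 CPM against 0.835 in the next male (0.674), and Btbd18 in control male 4 held 0.256 against 0.120 (0.707).

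Divisions of the 6 dams with as many genes as the real one numbered 10 of 10 for every comparison of alcohol with control without block or covariate, since the real count was 0; the highest other count was 227 in interneurons, 677 and 1032 in intermediate progenitors and excitatory neurons of males, 26 in microglia, 1 in Cajal-Retzius and erythroid cells, and 0 elsewhere. With the mitochondrial share as covariate 1 of 10 divisions gave as many genes, the real one, by dam in intermediate progenitors (34, highest other 4) and excitatory neurons (153, highest other 1) and in females in the same classes (1154, highest other 4; 3436, highest other 1); 10 are too few for a share under 0.05. Elsewhere other divisions gave more genes than the real one with this covariate: by dam in radial glia (4, highest other 7), in radial glia of females (1, highest other 7), and in radial glia, intermediate progenitors and excitatory neurons of males (0, 1 and 0, highest other 42, 5 and 12). Across genes the fitted change followed the slope of the covariate (r = 0.496, 0.590, 0.678 and 0.774 in intermediate progenitors and excitatory neurons by dam and then in those of females); a limit first set for these values was dropped and no p was computed. For male against female 5 of 100 divisions of the samples gave at least 7 genes, the real one among them. The others (4852, 2697, 3648 and 5686 genes) parted the samples of at most 2 dams, so they mostly compared dams with dams. Drawn divisions that parted all 6 dams, as sex does, gave 0 genes.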

How the results depend on the processing

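Of 319 alternative counts for the comparisons of alcohol with control, 280 stayed at 0 and 39 gave 1 gene or more; the cause was not tested. DESeq2 gave 2 genes in all cells, 2 in intermediate progenitors, 2 in those of females and 1 in excitatory neurons of females. The replicate block by title number, which pairs alcohol and control dams 1 and 3 of the titles, gave 2 genes in all cells, 4 in radial glia, 3 in intermediate progenitors, 1 in excitatory neurons, 69, 5 and 12 in these classes of males, 1, 2 and 2 in those of females, 3 in Cajal-Retzius cells, 99 in erythroid cells and 6 in microglia. Alcohol dam 12 and control dam 8 have title numbers of their own and add nothing to this contrast. It rests on the pairs of titles 1 and 3, with 1 residual degree of freedom. The block by description number gave 15 genes in erythroid cells. Without the filter on low counts there was 1 gene in intermediate progenitors, 2 in those of males, 3 in those of females, 11 in Cajal-Retzius cells, 6 in erythroid cells and 17 in microglia. Stricter cells gave 1 gene in intermediate progenitors of males. With the mitochondrial share as covariate, chosen after the data were seen, there were 4 genes in radial glia, 34 in intermediate progenitors, 153 in excitatory neurons, 3 in interneurons, 8 in Cajal-Retzius cells, 1 in intermediate progenitors of males, and 1, 1154 and 3436 in radial glia, intermediate progenitors and excitatory neurons of females. The interaction with dam as replicate block gave 396 and 694 genes in intermediate progenitors and excitatory neurons. With an estimated correlation and with fry, 0 gene lists passed in each of the 11 comparisons. With 1 replicate left out, chosen after the lists were seen, the median of 12 of 68 passed lists turned and 64 turned or moved by more than 1.5 times. With 1 replicate left out counts ran from 0 to 497 in intermediate progenitors of males, 0 to 4 in erythroid cells, 0 to 8 in microglia, 7 to 8 for sex, and stayed at 0 elsewhere. Over 61 alternative values of shares directions turned in 14; with all dams kept the smallest exact p was 0.3, and as 3 against 3 dams give 0.1 at best, none could pass. The radial glia difference of 1.95 points became −1.47 with stricter cells. That of intermediate progenitors (0.0340) became −0.172 without doublet removal, −0.395 with stricter cells, −0.343 at resolution 0.5, −0.843 over neural classes only, −1.09 in females, −0.989 without shallow clusters and −0.910 without clusters led by 1 sample. That of excitatory neurons (1.13) became −0.619 over neural classes only and −1.54 without shallow clusters. With 1 replicate left out the differences ran from −0.43 to 4.11 for radial glia, −1.83 to 0.99 for intermediate progenitors, 0.19 to 1.60 for excitatory neurons and −0.35 to 1.17 for interneurons. With 3 dams per treatment and 2868 to 8432 median UMIs per cell, log2 changes of 1 were recovered at 50% to 64% by dam in simulated counts. The changed genes had a mean of at least 10 CPM. Smaller changes, and changes of genes below that mean, were not simulated.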

Other observations

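No test in this part was chosen before the result was seen. Haemoglobin RNA was present in progenitors and neurons of every sample. Haemoglobin summed to 149, 560, 3072, 1013, 580 and 1622 CPM in intermediate progenitors of alcohol male 1, female 1, male 2, female 2, male 3 and female 3, and to 188, 202, 252, 193, 442 and 285 CPM in control male 1, female 1, male 3, female 3, male 4 and female 4. Between 31.5% and 95.1% of intermediate progenitors of a sample held at least 1 haemoglobin UMI.

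Gm42418, which overlaps 45S ribosomal RNA, was among the genes that moved with the mitochondrial share as covariate in excitatory neurons (0.86 ± 0.115 higher in alcohol dams, adjusted p = 0.00578), together with AC149090.1 (0.69), the neuronal factor Pou3f2 (0.59 ± 0.0988, adjusted p = 0.032), Dap (−0.72) and Trnp1 (−0.58). In radial glia the same covariate gave Hbb-bt, Hbb-y, Hba-a2 and AC149090.1, where another division of the dams gave 7 genes.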
